A study of Mus musculus with 23 samples.

How the data were processed

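Nascent transcription was measured by PRO-seq (precision run-on sequencing, in which engaged RNA polymerases incorporate biotinylated nucleotides in isolated nuclei) in forebrain of wild-type (WT) and Mecp2 knockout (KO) mice that were 8 weeks old and labelled male. The mice had received flavopiridol, an inhibitor of CDK9 in the kinase complex P-TEFb that releases paused polymerase, at 50 mg per kg into the peritoneum, and tissue was taken 20, 40 or 60 min later. The group labelled 0 min received vehicle and was dissected after 40 min, so it was matched in time since injection to the 40 min groups alone. The table held 23 libraries in 8 groups, with 2 libraries of KO at 20 min and 3 in every other group.

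The authors deposited 1 table of raw counts of PRO-seq reads per gene, assigned to the transcription start site. Per the labels, Bowtie2 2.2.9 and bedtools 2.26.0 were used with the genome build mm10. The window around the start, the strand rule, the handling of duplicate reads and the annotation were not given in the sources used here. The table was checked to hold whole numbers in 24498 genes, 1979 of them with no count in any library, and 0 columns were without a sample. Of 14253 genes with a mean of at least 20 counts, 62 had the same counts as another gene in all libraries (0.43%). Gene positions, lengths and biotypes came from the NCBI RefSeq annotation of the same build, to which 99.7% of the symbols were matched (23530 by symbol and 888 by a synonym). No reference genome was at hand, so GC content was not examined. No spike-in was stated, and every change is therefore relative to the other genes of the library, by the scaling used.

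Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr with the 8 groups were kept (17018 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 23 libraries. The comparisons were KO minus WT at each of the 4 times and averaged over the 4 times with equal weight, flavopiridol minus 0 min at each time within each genotype and averaged over times and genotypes, and the genotype by time interaction. P-values were adjusted by Benjamini-Hochberg within each comparison, and 0.05 was the threshold. Standard errors (SE) of log2 changes were derived from the quasi-likelihood F statistic. Levels per group are means of CPM (counts scaled to a common library total) after TMM scaling, with the standard deviation (SD) between libraries.

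The long gene score of a library was the mean log2(CPM + 1) of tested genes longer than 100 kb minus the mean over all other tested genes, over the 16971 tested genes with a length. It was compared by exact permutation tests, two-sided, that reassigned genotype within each time or treatment within each genotype (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, figures with matplotlib 3.10.9). The 25 gene lists, written from general knowledge of the tissue and the drug, covered drug and stress responses, long and synaptic genes, genes reported altered in Mecp2-mutant brain, and cell type and region markers. Lists with at least 3 tested members (24 of the 25) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Counts of list members passing are given over all genes tested and, where they differ, adjusted over the list alone.

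The comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Mecp2 and its neighbour Irak1 first. It then named, per comparison, up to 10 genes in each direction with the largest changes past the threshold, a mean of at least 20 counts and no overlap between the compared groups (for averaged comparisons, the same sign in every stratum). Where fewer than 5 passed, the genes with the smallest p were named, up to 5, as not passing. Up to 4 members of each list were named, those with the smallest adjusted p. Genes named outside the rule are given as chosen after their values were seen.

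The alternatives were median-of-ratios scaling, scaling by library totals alone, DESeq2 1.42.0 in place of edgeR, no filter on low counts, a minimum mean of 50 counts, only the groups compared, the replicate number as a block, and leaving out each library. For the long gene score they were length thresholds of 50 and 200 kb, pseudocounts of 0.1 and 5, and the median over genes. Leaving out 2 doubted libraries at 0 min, or all of 0 min, was added after the data were seen. The labels do not say that a replicate number pairs libraries, so the number was left out of the model.

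The pipeline was tested on simulated data in which groups of 50 genes were changed by 0.5, 1, 1.5 or 2 on the log2 scale in both directions. For KO minus WT at 60 min, 44%, 80%, 98% and 100% of these genes were recovered, with 12 false calls among 173. For KO minus WT averaged over the times, 86% were recovered at 0.5 and 100% at each larger change, with 15 false calls among 208. For the averaged flavopiridol comparison 80%, 94%, 98% and 100% were recovered, with 11 false calls among 197. A list of 60 genes moved by 0.3 had a camera adjusted p of 2.96e-12 with an estimated correlation, and 0 of the other lists were called at an adjusted p under 0.05 by camera or fry. The simulated genes were drawn independently of each other. The list test therefore cannot show how often the preset correlation gives false calls where the genes of a list move together. A long gene score raised by 0.1 was estimated at 0.093 (exact permutation p = 1.25e-05), and an unchanged one at 0.002 (exact permutation p = 0.474).

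Total counts per library ranged from 4.19 to 11.56 M (M for mega). The gene with the highest count in a library held 0.0419% to 0.0935% of its counts. Errors and intervals cover the spread between libraries or counting error only, since reads without molecular identifiers are not independent molecules.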

Results

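Nascent transcripts at gene starts were counted in 23 forebrain PRO-seq libraries. WT mice gave 3 libraries each at 0, 20, 40 and 60 min after flavopiridol, and KO mice gave 3, 2, 3 and 3 libraries at the same times, where 0 min stands for vehicle. Total counts, in M for mega, were 4.35, 5.84 and 4.63 M in WT at 0 min, 6.93, 8.41 and 5.67 M at 20 min, 9.88, 9.06 and 7.27 M at 40 min, and 9.68, 10.16 and 8.55 M at 60 min (replicates 1 to 3). In KO they were 4.8, 5.39 and 4.19 M at 0 min, 8.53 and 4.94 M at 20 min, 6.94, 11.56 and 8.24 M at 40 min, and 8.47, 10.67 and 8.87 M at 60 min. Total counts at gene starts were therefore higher after the drug, from 4.94 ± 0.79 (SD, n = 3) at 0 min to 9.46 ± 0.83 M (SD, n = 3) at 60 min in WT. These totals are not sequencing depth, since the numbers of reads sequenced or mapped were not at hand. The first principal component (59.1% of the variance) separated the 6 vehicle libraries from the 17 treated ones. In the library labelled WT 60 min replicate 1, Xist (X-inactivation RNA) had 384 counts and the sum of the Y-linked genes Uty, Ddx3y, Kdm5d and Eif2s3y was 2. The other 22 libraries had at most 2 counts of Xist and 302 to 1581 of the Y-linked genes. The counts of WT 60 min replicate 1 thus go against its male label, and the library was kept in the comparisons. With no filter on low counts edgeR called Xist, chosen after its values were seen, lower in KO at 60 min (-8.01 ± 1.4, SE, adjusted p = 0.0132). That call rests on this library.

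Counts at the start of Mecp2 (X, 74026592 to 74085690, mm10), which encodes a protein that binds methylated DNA, were similar in both genotypes. The mean levels at 0, 20, 40 and 60 min were 56.8, 103, 97 and 93.2 CPM in WT and 55.6, 94.6, 102.5 and 87.4 CPM in KO. KO minus WT averaged over the times was -0.04 ± 0.065 on the log2 scale (SE, n = 11 KO and 12 WT, adjusted p = 0.91 with edgeR). Counts at a gene start do not test the deletion, which can leave the promoter in place. After flavopiridol Mecp2 rose by 0.77 ± 0.078 averaged over times and genotypes (SE, adjusted p = 6.16e-09).

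Irak1 (X, 74013914 to 74023921), a kinase of interleukin-1 receptor signalling and the neighbour of Mecp2, was lower in KO. Its mean levels in WT at 0, 20, 40 and 60 min were 42.0, 64.2, 68.4 and 74.0 CPM. In KO they were 28.8, 17.7, 21.2 and 28.2 CPM. KO minus WT averaged over the times was -1.37 ± 0.17 (SE, 2.59-fold lower, adjusted p = 0.000213). At 20, 40 and 60 min it was -1.87 ± 0.40, -1.71 ± 0.33 and -1.39 ± 0.32, and these single times missed the threshold (adjusted p = 0.508, 0.167 and 0.173). At 0 min 2 libraries went against their labels. The library labelled WT 0 min replicate 3 had 14.3 CPM (73 counts) beside 58.3 and 53.4 CPM in the other WT libraries, and the library labelled KO 0 min replicate 2 had 51.2 CPM (315 counts) beside 17.3 and 18 CPM. With only the compared groups in the fit, which leaves 0 min out, Irak1 passed at 20, 40 and 60 min (-1.87 ± 0.13, -1.71 ± 0.16 and -1.39 ± 0.1, adjusted p = 0.000106, 0.0131 and 7.01e-06). Leaving out the 2 libraries tests nothing at Irak1, since they were doubted for their Irak1 counts. The microRNA genes Mir718 and Mir5132 lie at the same start as Irak1, so their values (-1.37 ± 0.17 and -1.41 ± 0.17 averaged) are not separate evidence.

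**Figure D1:**
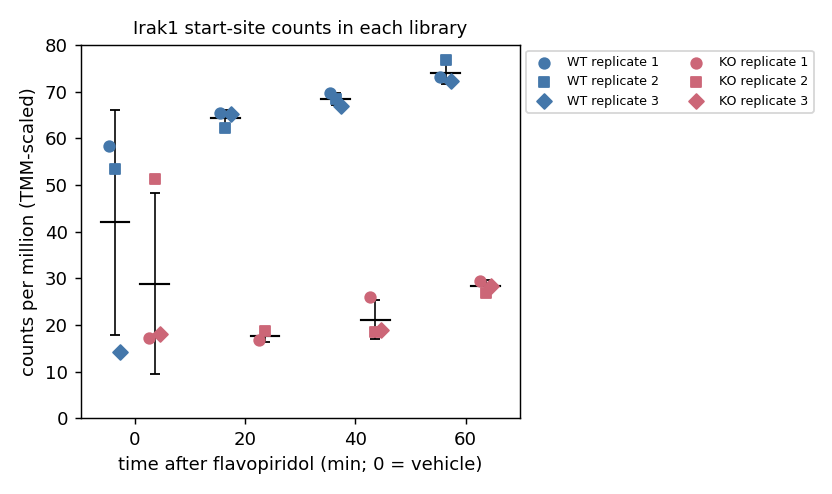
CPM at the start of Irak1 by time after flavopiridol (min) in each library, with the mean and SD per group for WT and KO. At 20, 40 and 60 min every KO library lies below every WT library; at 0 min the library labelled WT replicate 3 lies at 14.3 CPM and the library labelled KO replicate 2 at 51.2 CPM.

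KO was compared with WT at each time to ask whether loss of MeCP2 changes polymerase at gene starts with and without the block of pause release. At 60 min 3 genes fell in KO. Arhgdig (17, 26199183 to 26201350), a Rho GDP-dissociation inhibitor, changed by -1.10 ± 0.14 (SE, adjusted p = 0.00159) and kept its call without any 1 of the 6 libraries at 60 min (adjusted p from 0.00507 to 0.0495). Cacna1g (11, 94408391 to 94474400), a T-type calcium channel, changed by -0.90 ± 0.15 (adjusted p = 0.0153). It kept its call without WT 60 min replicate 1 or KO 60 min replicate 3 and lost it without WT 60 min replicate 2, WT 60 min replicate 3, KO 60 min replicate 1 or KO 60 min replicate 2 (adjusted p = 0.126, 0.141, 0.148 and 0.195). Fgf11 (11, 69796068 to 69802944), a fibroblast growth factor homologous factor, was 11.4 ± 0.70 CPM in WT and 3.19 ± 0.45 in KO (SD, n = 3 each), a log2 change of -1.83 ± 0.30 (SE, adjusted p = 0.0153). It lost its call without any 1 of the 6 libraries at 60 min (log2 change from -1.95 to -1.76, adjusted p from 0.0664 to 0.195). Podn, chosen after its values were seen, was called without KO 60 min replicate 1 (-1.79 ± 0.27, adjusted p = 0.0111). The calcium sensor Doc2a (-0.95 ± 0.18) and B830017H08Rik (-0.80 ± 0.16) missed the threshold at 60 min (adjusted p = 0.112 and 0.117). At 40 min Fgf11 had -1.55 ± 0.31 and G630025P09Rik -1.41 ± 0.29 (adjusted p = 0.18 and 0.205), and at 20 min Comtd1 had -0.62 ± 0.13 and Pnma2 -0.61 ± 0.15 (adjusted p = 0.508 and 1). At 0 min the smallest p belonged to Serpini1 (0.40 ± 0.12), Usp29 (0.38 ± 0.12), Sec13 (-0.37 ± 0.12), Ramp1 (-0.38 ± 0.12) and Gm7120 (-0.52 ± 0.17), all with an adjusted p of 1.

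Of 17018 genes, edgeR called 0, 0, 0 and 3 at 0, 20, 40 and 60 min, with 139, 591, 1150 and 931 genes at an unadjusted p under 0.05, and DESeq2 called 0, 0, 1 and 20. With only the compared groups in the fit the counts were 0, 3, 3 and 11, with Irak1, Mir718 and Mir5132 among those at 20, 40 and 60 min. With the 2 doubted libraries left out they were 3, 3, 3 and 7, of which the Irak1, Mir718 and Mir5132 calls follow from the choice of libraries and are not evidence. At 40 min Fgf11 was called without KO 40 min replicate 1, and 5 other genes (Snord45b, Fam83e, Wbp11, Rnf225 and 1700019N19Rik, chosen after their values were seen) without KO 40 min replicate 3.

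Averaged over the 4 times, 25 genes were higher and 83 lower in KO, with a median size of 0.41 on the log2 scale. With library totals alone 15 were higher and 85 lower, and 91 of the 108 calls were shared. The higher genes included Igf2bp2, an RNA-binding protein (0.94 ± 0.17, adjusted p = 0.00627), the transcription factors Tshz1 (0.55 ± 0.11, 0.0156) and Sox4 (0.46 ± 0.07, 0.00129), the zinc finger gene Zfp516 (0.52 ± 0.096, 0.00943) and the axon guidance ligand Efna5 (0.44 ± 0.077, 0.00553). Sox4 stood at 43.4 to 48.7 CPM in the WT groups and 59.5 to 69.0 CPM in the KO groups. Hs3st3a1, Nhsl2, Mir7655, Bmper and Gldc were higher by 0.48, 0.48, 0.41, 0.37 and 0.36. Besides Irak1, the lower genes included Fgf11 (-1.27 ± 0.17, adjusted p = 0.000247), the neuropeptide gene Grp (-0.78 ± 0.15, 0.00999), the kinase Cdk18 (-0.74 ± 0.15, 0.0163), G630025P09Rik (-0.91 ± 0.15, 0.00298) and AU022754 (-0.86 ± 0.14, 0.0034), with Rtbdn at -0.85 ± 0.18 and the signalling ligand Wnt7b at -0.81 ± 0.18.

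The genes higher in KO were long. Of the 25 higher genes 14 exceeded 100 kb, against 4 of the 83 lower genes (Fisher's exact test, odds ratio 25.1, p = 6.1e-08) and 12.8% of all tested genes. The median length was 104.3 kb for the higher genes, 11.7 kb for the lower genes and 19.2 kb for all tested genes. This length test was chosen after the calls were seen. It takes genes as independent, although all were measured in the same libraries, so its p does not measure the spread between animals. The lower genes also include Irak1, Mir718 and Mir5132, which share a start, and Slc10a3 and Gm44504, which overlap. With library totals alone 8 of 15 higher and 3 of 85 lower genes exceeded 100 kb (Fisher's exact test, p = 4.62e-06). Leaving out 1 library gave 6 higher genes, 5 of them over 100 kb (without KO 20 min replicate 1), to 45, 26 of them over 100 kb (without WT 40 min replicate 1). Over the alternatives run, p in Fisher's exact test was at most 0.000141 (without KO 20 min replicate 2). In unadjusted terms 1671 genes had p under 0.05, and DESeq2 called 201, of which 106 were among the 108. The count was 145 without the 2 doubted libraries. Leaving out 1 library moved the count to 31 (KO 20 min replicate 1), 46 (WT 0 min replicate 1, KO 0 min replicate 1 or KO 0 min replicate 3), 54 (WT 0 min replicate 2), 62 (WT 40 min replicate 2), 64 (KO 60 min replicate 2 or 3), 68 (KO 40 min replicate 2), 71 (WT 60 min replicate 2) or 177 (KO 40 min replicate 1).

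The long gene score asked whether genes over 100 kb, 2179 of the 16971 with a length, stood higher relative to other genes in KO. The score was higher in KO by 0.039 (exact permutation p = 0.00406 over 80000 reassignments). At 0 min the groups were alike, 0.017 ± 0.026 in WT and 0.015 ± 0.03 in KO (SD, n = 3 each; difference -0.002, exact permutation p = 1). At 20 min the score was 0.022 ± 0.01 in WT (n = 3) and 0.078 ± 0.041 in KO (n = 2), at 40 min 0.036 ± 0.017 and 0.088 ± 0.044 (n = 3 each), and at 60 min 0.028 ± 0.023 and 0.079 ± 0.003 (n = 3 each). These differences of 0.056, 0.052 and 0.051 had exact permutation p-values of 0.1, 0.2 and 0.1, where 0.1 was the smallest the design allows. Over the 17 libraries at 20, 40 and 60 min alone, a choice made after seeing the data, the difference was 0.053 (exact permutation p = 0.00075).

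**Figure D2:**
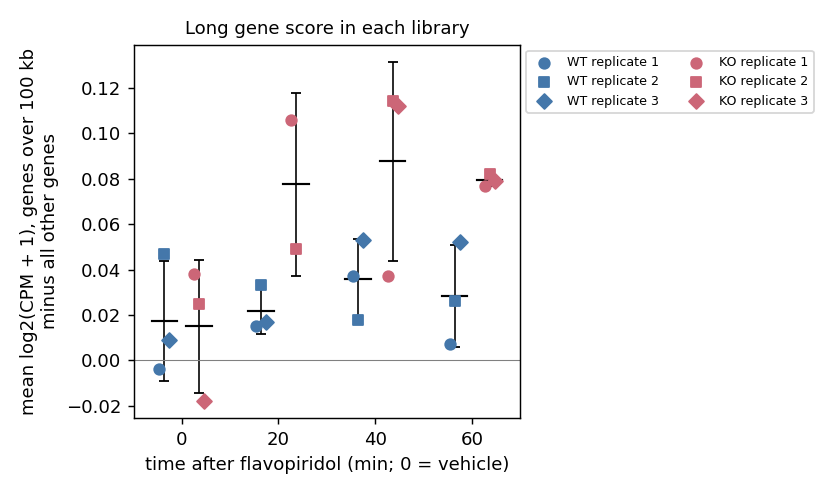
Long gene score (mean log2(CPM + 1) of genes over 100 kb minus that of all other tested genes) by time after flavopiridol (min), with 1 point per library and the mean and SD per group. KO groups average 0.078, 0.088 and 0.079 at 20, 40 and 60 min and WT groups 0.022, 0.036 and 0.028; at 0 min they average 0.015 in KO and 0.017 in WT.

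Among the gene lists, inhibitory neuron markers stood higher in KO averaged over the times. None of the 14 tested passed over all genes and 8 were higher adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.000113, and adjusted p = 0.29 with an estimated correlation). Adarb2 had 0.28 ± 0.077 and the homeobox gene Dlx2 0.40 ± 0.12, with adjusted p of 0.099 and 0.135. Of 60 very long neuronal genes 2 were higher, the ubiquitin ligase gene Park2 (0.27 ± 0.051, adjusted p = 0.0138) and the axon guidance receptor Robo1 (0.35 ± 0.079, adjusted p = 0.0346). The median of that list was 0.09 (camera adjusted p = 0.00178, and adjusted p = 0.425 with an estimated correlation). At 60 min it was 0.26, with 0 genes over all and 2 adjusted over the list alone (camera adjusted p = 9.91e-12, and adjusted p = 0.168 with an estimated correlation). Immediate-early and activity-regulated genes had a median of 0.1 with 0 of 49 passing (camera adjusted p = 0.00178, adjusted p = 0.168 without KO 40 min replicate 1, and adjusted p = 0.513 with an estimated correlation). The largest member values were Fos at 0.49 ± 0.16 and Fosb at 0.36 ± 0.13, with adjusted p of 0.193 and 0.253.

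Ribosomal protein genes (median 0.04), nuclear oxidative phosphorylation genes (0.04), heat shock genes (0.08), circadian clock genes (0.1) and olfactory bulb, dentate and neurogenic markers (0.09) were also called upward in KO by camera, with adjusted p of 0.00524, 0.00347, 0.00347, 0.00642 and 0.0312. None of their members passed over all genes, and 3 of the neurogenic markers passed adjusted over the list alone. With an estimated correlation their adjusted p was 0.688, 0.513, 0.294, 0.294 and 0.29. Calls were also lost on leaving out 1 library. The ribosomal list lost its call without replicate 3 of WT at 20, 40 or 60 min (adjusted p = 0.075, 0.114 and 0.082), KO 20 min replicate 1 (0.123) or KO 40 min replicate 1 (0.293). The neurogenic list lost it without WT 40 min replicate 3, WT 60 min replicate 3, KO 0 min replicate 2, KO 20 min replicate 1 or KO 40 min replicate 1 (adjusted p = 0.0623, 0.0527, 0.0519, 0.0899 and 0.0678). It also lost its call with the replicate block (camera adjusted p = 0.0543), without the 2 doubted libraries (0.0601) and without 0 min (0.0572). The oxidative phosphorylation list lost it without WT 40 min replicate 3 or KO 20 min replicate 1 (0.092 and 0.112), the heat shock list without KO 20 min replicate 1 (0.0899) and the circadian list without KO 40 min replicate 1 (0.0568). Oligodendrocyte precursor markers stood lower in KO (median -0.14, 0 of 10 passing, camera adjusted p = 0.00569, adjusted p = 0.0568 without KO 40 min replicate 1, and adjusted p = 0.29 with an estimated correlation). Among 15 genes reported altered in Mecp2-mutant brain, Irak1 fell over all genes, and 3 were higher and 2 lower adjusted over the list alone, in a list called for change in either direction (fry mixed adjusted p = 4.78e-07). Its median was 0.05 and its mean -0.03, with camera pointing up (adjusted p = 0.162). The synaptic list had 1 lower gene of 35, the inhibitory synapse adhesion gene Nlgn2 (-0.96 ± 0.22, adjusted p = 0.0369), with a list median of 0.01, a mean of -0.03 and camera pointing down (adjusted p = 0.789). The other 13 tested lists had camera adjusted p over 0.05 in this comparison. Of these, 8 were called in at least 1 fit without 1 library (glucocorticoid-responsive, P-TEFb, NF-kB and histone genes, and astrocyte, striatal, endothelial and choroid plexus markers), with medians from -0.18 to 0.1. The glucocorticoid-responsive list was also called with median-of-ratios scaling (camera adjusted p = 0.0499) and with library totals alone (0.0491). It was called as well without the 2 doubted libraries (0.0206), as were the P-TEFb and NF-kB lists (0.0354 and 0.0295), and without 0 min (0.0088), as were the P-TEFb and astrocyte lists (0.0475 and 0.0209).

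Flavopiridol changed counts at 51.4%, 57.8% and 62.2% of gene starts in WT and 45.8%, 61.1% and 61.7% in KO at 20, 40 and 60 min. In WT 4688, 5093 and 5384 genes were higher and 4065, 4747 and 5195 lower at these times than at 0 min. In KO 4231, 5340 and 5299 were higher and 3566, 5066 and 5208 lower. Averaged over times and genotypes, 6257 genes were higher and 6550 lower (75.3% of the tested genes), with a median size of 0.64. The histone methyltransferase gene Kmt2d (15, 98831669 to 98874077) rose by 1.63 ± 0.10 (adjusted p = 5.38e-12), from 22.4 ± 5.0 CPM in WT vehicle to 53.9 ± 4.6, 68.9 ± 8.5 and 84.9 ± 5.0 CPM (SD, n = 3 each). Tsc22d2 (1.55 ± 0.085), the ubiquitin ligase gene Rbbp6 (1.56 ± 0.10), the translation initiation factor gene Eif2s3x (1.56 ± 0.13), Rhoh (1.59 ± 0.23) and the unnamed transcripts R74862 (1.69 ± 0.084), 4930513N10Rik (1.60 ± 0.16) and 4930488L21Rik (1.54 ± 0.069) rose by similar amounts. The melanocortin receptor gene Mc1r (8, 123407082 to 123410744) fell by 4.21 on the log2 scale (SE 0.22, adjusted p = 6.38e-13), from 22.5 ± 5.4 CPM in WT vehicle to 1.72 ± 0.93, 1.13 ± 0.92 and 0.89 ± 0.49 CPM. Doc2g (-4.53 ± 0.22), Mir130a (-4.57 ± 0.30), Lsmem1 (-4.24 ± 0.27) and Mir7040 (-4.28 ± 0.26) fell to a like degree.

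At single times the endothelial gene Robo4 (2.10 ± 0.37, adjusted p = 7.05e-05), the growth factor receptor gene Pdgfra (2.00 ± 0.30, 1.43e-05) and the synaptic gene Syngap1 (1.59 ± 0.16, 2.76e-07) were among the largest rises in WT at 20 min. In KO at 20 min they included Klhl34 (1.96 ± 0.32, adjusted p = 3.96e-05), the RNA-binding protein gene Pcbp1 (1.88 ± 0.25, 5.72e-06), Hif3a (1.74 ± 0.18, 5.29e-07) and the anti-apoptotic gene Bcl2l1 (1.67 ± 0.18, 7.31e-07). At 60 min Kmt2d (1.93 ± 0.16 in WT, 1.91 ± 0.16 in KO) and Rbbp6 (1.91 ± 0.16 and 1.84 ± 0.16) were among the largest rises in both genotypes, below Mir6403 (2.18 ± 0.42 and 2.24 ± 0.41). Across the 17018 genes, which are not independent replicates, the changes in WT and KO had Pearson's r of 0.905, 0.914 and 0.938 and Spearman's rho of 0.9, 0.933 and 0.946 at 20, 40 and 60 min.

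The direction of single genes depends on the scaling, since no spike-in was stated. With library totals alone the median averaged change of all genes moved from -0.033 to -0.264, and 4146 genes were called higher and 8709 lower. By time that scaling gave 3059, 3127 and 3358 higher and 5707, 6486 and 6923 lower genes in WT, and 2684, 3247 and 3228 higher and 5411, 7147 and 6872 lower genes in KO. The 20 genes with the largest averaged changes kept their direction and call under it.

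Averaged over times and genotypes, 5 lists were called higher after flavopiridol by camera at the preset correlation and none of them with an estimated one. Of 78 ribosomal protein genes 69 rose and 1 fell (median 0.6, camera adjusted p = 7.88e-11, and 0.552 with an estimated correlation), with Rps18 at 0.96 ± 0.062 and Rpl18a at 1.15 ± 0.092. Of 75 nuclear oxidative phosphorylation genes 67 rose and 4 fell (median 0.59, camera adjusted p = 9.12e-12, and 0.446 with an estimated correlation), with the ATP synthase gene Atp5o at 1.02 ± 0.065 and the complex I gene Ndufs3 at 1.03 ± 0.069. Of 37 genes of P-TEFb, pausing and elongation 26 rose and 7 fell, or 27 and 7 adjusted over the list alone (median 0.37, camera adjusted p = 0.00189, and 0.446 with an estimated correlation). They included the cyclin T gene Ccnt1, a partner of CDK9 (1.15 ± 0.084), the bromodomain genes Brd4 (0.98 ± 0.066) and Brd2 (1.15 ± 0.09), and the elongation factor gene Supt6 (1.03 ± 0.083). Of 35 synaptic genes 26 rose and 4 fell (median 0.4, camera adjusted p = 0.000666, and 0.394 with an estimated correlation), with the postsynaptic scaffold gene Dlg4 at 1.19 ± 0.076 and Syngap1 at 1.32 ± 0.1. Of 18 heat shock and chaperone genes 13 rose and 4 fell (median 0.59, camera adjusted p = 0.0394, 0.0504 without WT 0 min replicate 3, and 0.552 with an estimated correlation), with Hspd1 at 0.8 ± 0.058 and Hspe1 at 0.75 ± 0.057.

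The replication-dependent histone genes fell, 52 of 68 lower and 4 higher (median -0.72, camera adjusted p = 2.21e-06, and 0.552 with an estimated correlation), with Hist1h2be at -1.71 ± 0.15, Hist4h4 at -1.19 ± 0.11 and Hist1h2bc at -0.85 ± 0.083. The very long neuronal genes fell as well, 29 of 60 lower and 6 higher (median -0.31, camera adjusted p = 0.0281, and 0.552 with an estimated correlation), with the catenin gene Ctnna3 at -1.7 ± 0.13, Robo1 at -1.05 ± 0.085, Immp2l at -0.85 ± 0.087 and Macrod2 at -0.64 ± 0.071. Their median in WT was -0.13, -0.36 and -0.53 at 20, 40 and 60 min, and in KO -0.09, -0.31 and -0.32. With library totals alone the medians of these 7 lists were lower by about the shift of all genes and kept their sign.

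**Figure D3:**
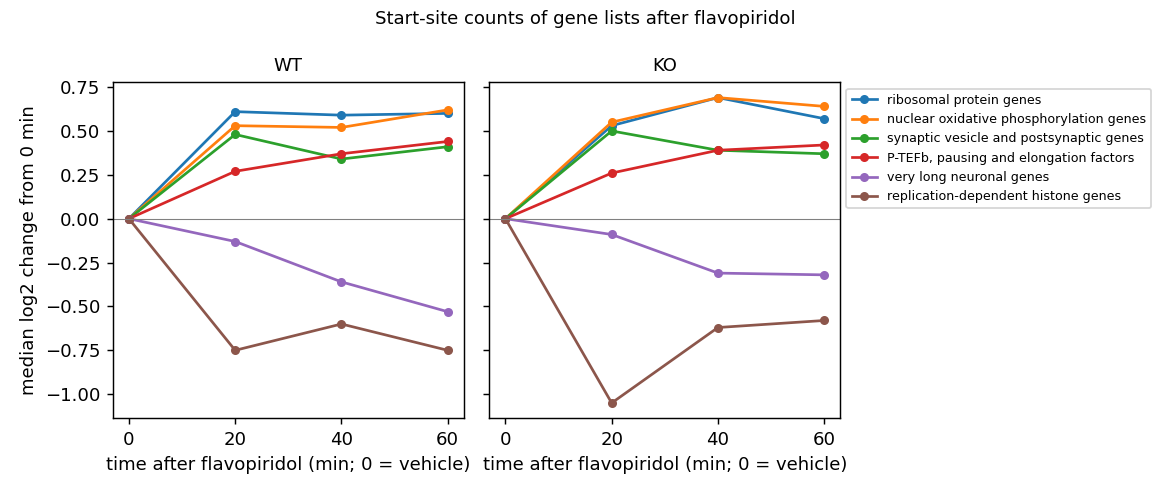
Median log2 change after flavopiridol of the gene lists against time (min), in WT and KO. Ribosomal protein genes lie between 0.53 and 0.69 and replication-dependent histone genes between -1.05 and -0.58, and these keep their sign with library totals alone; the very long neuronal genes reach -0.53 in WT and -0.32 in KO at 60 min.

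Stress and signalling lists went both ways, and camera called none of them after averaging. Of 17 NF-kB and cytokine genes 9 fell and 2 rose (median -0.34, camera adjusted p = 0.13), with the subunit genes Relb at -1.48 ± 0.1 and Nfkb2 at -0.91 ± 0.089 and the interferon regulator Irf1 at -1.13 ± 0.094. Of 20 p53 target genes 11 fell and 6 rose (median -0.24, camera adjusted p = 0.407), with Sesn2 at -0.73 ± 0.065 and Bax at 0.5 ± 0.052. Of 49 immediate-early and activity-regulated genes 16 rose and 17 fell (median -0.05, camera adjusted p = 0.759), with Pim1 at -0.99 ± 0.072, Klf4 at -0.9 ± 0.073 and Fbxo33 at 0.52 ± 0.045. Of 23 glucocorticoid-responsive genes 13 rose and 4 fell (median 0.29, camera adjusted p = 0.13), among them Hif3a (1.1 ± 0.1), Klf9 (0.94 ± 0.11) and Zbtb16 (0.85 ± 0.075). Of 18 circadian clock genes 11 rose and 4 fell (median 0.24, and 0 with library totals alone; camera adjusted p = 0.221), with Per1 at 0.99 ± 0.12 and Cry1 at -1.1 ± 0.096. Of the 15 genes reported altered in Mecp2-mutant brain 6 rose and 3 fell (median 0.29, camera adjusted p = 0.407), with Igfbp3 at -1.51 ± 0.079 and Sgk1 at 0.51 ± 0.067. With library totals alone the medians were lower, at -0.57 (NF-kB), -0.47 (p53), -0.29 (immediate-early), 0.06 (glucocorticoid-responsive) and 0.06 (reported altered).

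Camera called none of the cell type and region marker lists after averaging, and since 75.3% of all tested genes changed, the counts of members that changed are not particular to these lists. Microglia markers rose in 12 of 17 and fell in 2 (median 0.54, camera adjusted p = 0.0756, but 0.0181 with library totals alone, 0.0439 without WT 20 min replicate 1 and 0.0437 without KO 0 min replicate 2), with the complement genes C1qa at 1.14 ± 0.14 and C1qc at 1.02 ± 0.18. Oligodendrocyte markers rose in 12 of 19 and fell in 1 (median 0.39, camera adjusted p = 0.0821), with Olig2 at 0.86 ± 0.12 and Mbp at 0.53 ± 0.086. Astrocyte markers rose in 8 of 14 and fell in 3 over all genes, or 4 adjusted over the list alone (median 0.41, camera adjusted p = 0.235), with Gjb6 at 1.0 ± 0.14 and S100b at -0.57 ± 0.097. Excitatory neuron markers rose in 9 of 15 and fell in 1 (median 0.27, 0.19), and inhibitory neuron markers rose in 8 of 14 and fell in 3 (median 0.44, 0.221), with Lhx6 at 1.03 ± 0.14 and Gad2 at 0.81 ± 0.11. Striatal markers rose in 4 of 15 and fell in 4 (median 0.11, and -0.12 with library totals alone; camera adjusted p = 0.661). Oligodendrocyte precursor markers rose in 4 of 10 and fell in 2 (median 0.22, and -0.01 with library totals alone; camera adjusted p = 0.583), with Pdgfra at 1.5 ± 0.19. Endothelial and mural markers had 1 higher and 3 lower of 18 (median -0.03, camera adjusted p = 0.725), and choroid plexus and ependymal markers 2 higher and 4 lower of 11 (median -0.05, 0.553), with Foxj1 at -1.37 ± 0.2. Thalamus, hypothalamus and hindbrain markers had 4 lower of 9 (median -0.17, 0.407), and olfactory bulb, dentate and neurogenic markers 2 higher and 7 lower of 14 (median -0.32, 0.237), with the proliferation genes Mki67 at -1.26 ± 0.15 and Top2a at -1.11 ± 0.16. With library totals alone the median of excitatory markers was 0.04. Under that scaling the medians of the marker lists lay between 0.31 (microglia) and -0.56 (olfactory bulb, dentate and neurogenic). Red blood cell markers had too few tested members for a test.

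Both ends of the length scale lost counts after flavopiridol, relative to the library. The median averaged change was -0.379 in genes under 5 kb, 0.03, 0.052 and 0.06 in genes of 5 to 20, 20 to 50 and 50 to 100 kb, and -0.022, -0.073 and -0.261 in genes of 100 to 200 kb, 200 to 500 kb and over 500 kb. Under 5 kb 906 genes were higher and 1738 lower, and over 500 kb 35 were higher and 97 lower. The bins held genes of every biotype, and those under 5 kb include short microRNA and snoRNA genes. Of all tested microRNA and snoRNA genes 54.7% and 68% fell to less than 50%. Length and biotype were not told apart. The long gene score was higher after flavopiridol than at 0 min by 0.039 (exact permutation p = 0.00543 over 36300 reassignments), by 0.011 in WT (exact permutation p = 0.382) and by 0.067 in KO (exact permutation p = 0.0121). That direction depended on the settings. The difference was -0.017 at a threshold of 200 kb (exact permutation p = 0.317), -0.019 with a pseudocount of 5 (p = 0.0968), -0.063 with the median over genes (p = 0.00314) and -0.095 in genes with a mean of at least 50 counts (p = 5.51e-05), so no direction can be given for genes over 100 kb.

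**Figure D4:**
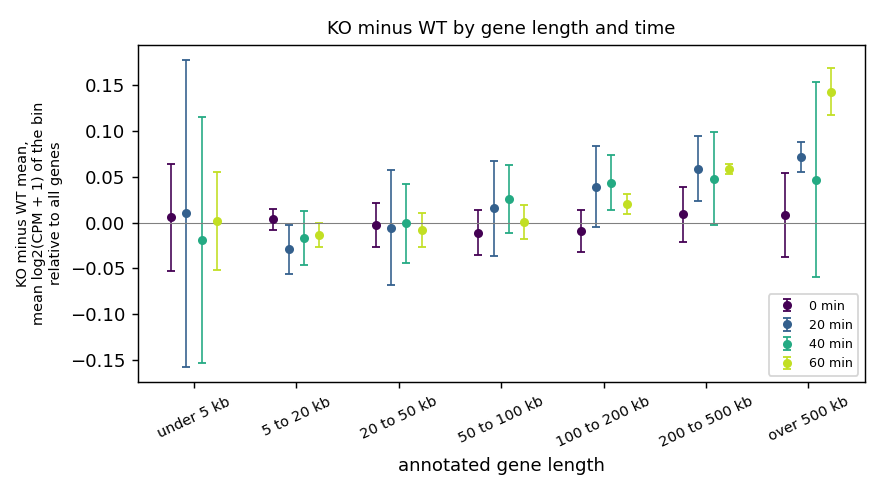
KO minus WT by gene length bin (kb) at each time: the mean log2(CPM + 1) of a bin in each KO library relative to all genes, minus the mean of WT at that time, as mean and SD over KO libraries. The fitted median over 500 kb was 0.008 at 0 min and 0.065, 0.043 and 0.133 at 20, 40 and 60 min.

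The interaction tested whether the response to flavopiridol differed between genotypes. EdgeR called 0 of 17018 genes, with 161 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and the likelihood ratio test of DESeq2 called 0. Irak1 changed by 0.81 ± 0.32 in WT at 60 min (adjusted p = 0.0306) and by -0.06 ± 0.34 in KO (adjusted p = 0.899), a difference not called by that test. Both values rest on the 2 doubted libraries. With these left out the values were 0.4 in WT and 0.68 in KO, given without a test because the libraries were chosen by their Irak1 counts. The call in WT was lost with library totals alone (0.56 ± 0.33, adjusted p = 0.138), with a mean of at least 50 counts (0.66 ± 0.32, adjusted p = 0.0796), on leaving out WT 0 min replicate 3 (0.4 ± 0.26, adjusted p = 0.188), and on leaving out WT 60 min replicate 1, 2 or 3 (adjusted p = 0.0609, 0.0716 and 0.0521).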

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

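The result below is a difference between times that was given a permutation p of its own. The tests by cell type markers and by total counts, the division of genes by count and the leaving out of 2 doubted libraries were chosen after it was seen; the tests by drug response and by thinning were not.

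In these libraries genes over 100 kb stood higher in KO than in WT under flavopiridol, by more than at 0 min. The KO minus WT difference in the long gene score at 20, 40 and 60 min exceeded that at 0 min by 0.055 (exact permutation test over 80000 reassignments of genotype within times, p = 0.0412). Such reassignment takes genotype to have no effect at any time. The p is therefore not a test of whether the genotype difference is equal with and without the drug. Without the 2 doubted libraries at 0 min the excess was 0.064 (exact permutation p = 0.0955), and the 0 min difference was -0.011 (exact permutation p = 0.667, where 0.333 is the smallest possible).

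Over the 1840 genes whose averaged flavopiridol change was within 0.1, the difference at 20, 40 and 60 min was 0.056 (exact permutation p = 0.003). Over all genes it was 0.053. This had been set as the bound against a weaker response to the drug in KO, but it cannot decide. The genes were chosen by the change averaged over both genotypes, and the bound of 0.1 is wider than the difference. A weaker response in KO therefore stays open. Total counts are argued against, since the mean totals at 20, 40 and 60 min were alike, 8.4 M in WT and 8.52 M in KO. The slope of the score on log2 total within groups was also taken out, which moved library scores by up to 0.034. The difference was then 0.055 (exact permutation p = 0.0005). With mean totals this alike, taking out the slope could hardly change that difference. Thinning every library to the same total of 4 M counts left it at 0.054, but random thinning could hardly move it and decides nothing. A higher share of neuronal nuclei in KO libraries cannot be told apart from a change within cells: it would lower the markers of every other cell type, and their medians at 20, 40 and 60 min went both ways, with the highest at 0.14 (astrocytes) and the lowest at -0.19 (oligodendrocyte precursors). Neither list passed by fry in limma (adjusted p = 0.325 and 0.108), and camera called both at the preset correlation (adjusted p = 0.0209 and 0.0045) and neither with an estimated one (adjusted p = 0.506 and 0.375). It would also raise neuronal markers, and of these the inhibitory list had the highest median of all lists, 0.23 (camera adjusted p = 0.00369, 0.506 with an estimated correlation, and fry adjusted p = 0.305), while the striatal list stood at 0.08 and the excitatory list at 0.02 (camera adjusted p = 0.162 and 0.982). The long gene difference was 0.077 in the lowest tertile of genes by mean count (exact permutation p = 0.0467), 0.068 in the middle tertile (p = 0.00075) and 0.012 in the highest (p = 0.473). An effect of MeCP2 loss on long genes stays open as a hypothesis, as does GC content, which could not be examined without a genome.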

How the results depend on the processing

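The alternatives that leave out the 2 doubted libraries or 0 min were chosen after the data were seen; the others were not. KO minus WT at single times moved in several settings, and the causes were not tested except where the genes show them. With no filter the counts at 20, 40 and 60 min were 3, 3 and 10, with only the compared groups 3, 3 and 11, and without the doubted libraries 3, 3, 3 and 7 at 0, 20, 40 and 60 min; in each setting Irak1, Mir718 and Mir5132 were among them, and without the doubted libraries these 3 calls follow from the choice of libraries by their Irak1 counts. DESeq2 gave 1 at 40 min and 20 at 60 min, and 201 averaged over the times. The replicate block gave 165 for the latter, with all 108 calls among them. Not every pair of a KO and a WT library with the same number and time deviated together (6 of 11 residual correlations over 0.1, range -0.42 to 0.572), yet 47 of all 77 same-number pairs were over 0.1, with a median of 0.132 against -0.09 for different numbers, and 12 of 23 libraries correlated best with their own number. This hints from the data, not the design, at a structure shared by number. The lowest correlation, -0.42, was that of replicate 2 at 20 min. KO 20 min replicate 1 correlated at 0.42 with WT 20 min replicate 2, against 0.107 with WT 20 min replicate 1. KO 20 min replicate 2 correlated at 0.451 with WT 20 min replicate 3. With 2 libraries in a group their deviations mirror each other. Whether the numbers of this group match the others was not tested, and the replicate block took them as given. Leaving out 1 library gave 0 at 0 and 20 min, 0 to 5 at 40 min, 1 to 2 at 60 min (fewer samples) and 31 to 177 averaged over the times (without KO 20 min replicate 1 and without KO 40 min replicate 1); the cause of the last was not tested. The flavopiridol counts stayed within 1.5 times in every setting, averaged from 12281 to 13132 when 1 library was left out, and the interaction gave 0 in every setting. The long gene score for KO minus WT stayed between 0.027 and 0.053 with p under 0.05 in every setting, and between 0.032 and 0.046 when 1 library was left out. Tertiles of genes by mean count were not among these settings. In the lowest, middle and highest tertile the score differed by 0.077, 0.068 and 0.012 over the treated libraries (exact permutation p = 0.0467, 0.00075 and 0.473). For flavopiridol minus 0 min it reversed at 200 kb (-0.017), with a pseudocount of 5 (-0.019), with the median (-0.063) and in genes with a mean of at least 50 counts (-0.095), and was 0.107 at 50 kb, 0.114 with a pseudocount of 0.1 and 0.031 to 0.046 when 1 library was left out; the cause was not tested. No named gene called for KO minus WT at 60 min or in an averaged comparison reversed, and no called list did. Among values that were not called, Irak1 averaged over times and genotypes after flavopiridol went from 0.14 to -0.1 with library totals alone and -0.07 without WT 0 min replicate 3, and in KO from -0.49 to 0.25 at 40 min and from -0.06 to 0.68 at 60 min without KO 0 min replicate 2. With library totals alone the flavopiridol medians of striatal and oligodendrocyte precursor markers went from 0.11 to -0.12 and from 0.22 to -0.01; medians of other uncalled lists that lay within 0.09 of 0 changed sign in some fits. Named genes lost their call in 104 fits without 1 library and kept it in 857. The estimated correlation ended all 16 camera calls of the averaged comparisons. Total counts limit the weakest genes: 3 counts in the smallest library are a level of 0.716 CPM.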

Other observations

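The label score of the 2 doubted libraries and the nesting of protein-coding genes were tested on predictions made before their results were seen. The tests of total counts of the doubted libraries, of falls at matched totals and of nesting in non-coding genes were chosen after. So were the division by biotype and the neighbourhood of Mecp2.

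A higher share of small RNA genes than of protein-coding genes lost counts after flavopiridol; no test of enrichment was run. Of 2738 genes that fell to less than 50% of their level, averaged over times and genotypes, 451 were microRNA genes (54.7% of the 825 tested) and 83 were snoRNA genes (68% of 122). Protein-coding genes made up 1897 of them (12.9% of 14667) and lncRNA genes 230 (20.6% of 1114). More than a doubling was seen in 449 genes, of which 405 were protein-coding, 31 lncRNA, 6 microRNA and 0 snoRNA genes. Library scaling bears on such counts, as given beside the calls for flavopiridol.

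Several gene lists differed between KO and WT at single times by camera, in opposite directions for the histone genes. Replication-dependent histone genes had a median of -0.21 at 20 min (camera adjusted p = 2.19e-05) and 0.16 at 60 min (camera adjusted p = 2.66e-05), with adjusted p of 0.68 and 0.936 with an estimated correlation. Inhibitory neuron markers had medians of 0.26, 0.2 and 0.19 at 0, 20 and 60 min (camera adjusted p = 2.34e-05, 0.00973 and 0.04, and 0.456, 0.545 and 0.936 with an estimated correlation). At 40 min ribosomal protein genes had a median of 0.14 and immediate-early genes 0.22 (camera adjusted p = 7.27e-07 and 0.000117, and 0.476 for both with an estimated correlation). Both medians include KO 40 min replicate 1, which stood apart from its group. Without that library the medians averaged over the 4 times went from 0.04 to 0.01 (ribosomal) and from 0.1 to 0.04 (immediate-early). At 60 min oligodendrocyte precursor markers had -0.33 (camera adjusted p = 0.00027, and 0.0607 with an estimated correlation). Microglia markers had -0.13 at 0 min (camera adjusted p = 0.0484, and 0.809 with an estimated correlation). No single member of these lists passed over all genes.

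Within 2 Mb of the start of Mecp2, 5 of 69 tested genes were called between KO and WT averaged over the times, against 103 of 16949 elsewhere. They were Irak1, Mir718 and Mir5132, which share a start, and Slc10a3 and Gm44504, which overlap each other (-0.37 ± 0.078 each, adjusted p = 0.0241). L1cam, a neural adhesion gene in that window, had -0.42 ± 0.11 and did not pass (adjusted p = 0.0837).

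The library labelled WT 0 min replicate 3 and the library labelled KO 0 min replicate 2 went against their labels at Irak1. In 97 autosomal genes of the 104 called between genotypes from the 17 treated libraries alone, a score placed WT 0 min replicate 3 at 0.077 and KO 0 min replicate 2 at -0.109 from the midpoint, where positive values are the KO side. The remaining libraries stood at -0.132 and -0.169 (WT) and at 0.155 and 0.146 (KO), so a difference at the Irak1 locus alone is argued against. A difference in total counts is argued against too. The lower total of the 2 libraries, 4.63 M counts, lay within the 4.19 to 5.84 M counts of the remaining 0 min libraries. A candidate explanation is exchanged genotype labels of these 2 libraries, since both lay on the other genotype's side of the midpoint. No biological explanation was tested.

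Genes that fell to less than 50% after flavopiridol may include starts that lie wholly inside another gene and carry its reads. A gene was counted as nested where its whole span lay inside a longer gene, on either strand. In protein-coding genes 5.3% of the 1897 falling genes were nested, against 2.4% of the 12770 others. Starts inside another gene whose own gene extends beyond it were not counted, so these shares set no upper bound. For protein-coding genes this explanation cannot be told apart. The median change was -0.23 in nested genes and 0.03 in the others, and over strata of mean count the odds ratio was 0.8 (95% interval 0.62 to 1.04). An interval that includes 1 had been set as the bound against this explanation, but that bound was wrong, because such an interval also holds values above 1. In non-coding genes the odds ratio was 2.25 (1.83 to 2.78), with 572 of 831 falling genes nested against 529 of 1473 of the rest, so reads of host genes stay open for these. Lower total counts at 0 min are not decided. The totals of WT 20 min replicate 3 and KO 20 min replicate 2 (5.67 and 4.94 M) lay within those of the 0 min libraries of their genotype. The median change of the falling genes was -1.07 in each, against 0.02 for all genes. These genes were chosen as falling in a comparison that includes both libraries and the same 0 min libraries. A negative median was therefore favoured by the choice. Thinning every library to 4 M counts moved the median over all libraries from -1.77 to -1.78, but random thinning could hardly move it and decides nothing. A direct effect of the drug on these starts stays open and was not tested separately.

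Other splits of the same libraries were counted for each comparison of groups of at least 3. For KO minus WT averaged over the times, 3 of 100 splits, the real one among them, gave as many genes as the real 108. The highest other was 408. Chance is argued against at that share but not excluded, since a split calling several times the real count points to a structure of the samples. For flavopiridol averaged over times and genotypes, 1 of 100 splits, the real one, reached the real 12807, with the highest other at 4040. Chance is argued against at that share, the smallest that 100 splits allow, but not excluded. For the interaction the real count was 0, which all 100 splits reach by construction, so the splits decide nothing; the highest other was 5. With 10 splits the share is never under 0.05, and the values were these. KO minus WT at 0 min had a real count of 0, which all 10 splits reach by construction, with a highest other of 3 from the split that exchanges the 2 doubted libraries. At 40 min it was 0, reached in all 10 likewise, with a highest other of 1250, which points to a structure of the samples, and at 60 min it was 3, reached in 1 of 10, with a highest other of 0. For flavopiridol in WT the real counts were 8753, 9840 and 10579 at 20, 40 and 60 min, and in KO 10406 and 10507 at 40 and 60 min, each reached in 1 of 10 splits with a highest other of 0.

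KO 40 min replicate 1 stood apart from its group. Its counts differed from those of its replicates with a chi-square per degree of freedom of 21.52 and 26.78, against 8.62 between the other 2. On the second principal component (15% of the variance) it lay at -54.2, beside 9.8 and 16.7 for the other 2 libraries of its group and -54.4 to -26.7 for the libraries at 20 min. On the first (59.1%) it lay at 50, beside 61.2 and 21.8 for those 2 libraries and -5.1 to 27.3 for the libraries at 20 min. On the fourth (3.2%) it lay at 41.5, against at most 11 in any other library. Without it, 177 genes were called for KO minus WT averaged over the times, against 108 with it.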
